A study of Mus musculus with 49 samples.

How the data were processed

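Gene expression was measured with 49 one-colour arrays (Cy5) of mouse cells in 23 groups, of which 20 groups held 2 arrays and 3 groups held 3. Whether the replicates of a group are separate cultures is not given, so a p-value measures the spread between arrays. The number of arrays limits the precision of every value.

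The deposited values are linear intensity values, one per probe and array. Software, background correction and normalization are not given in the sources used here. In the values themselves, the arrays fall into 5 sets: within a set the sorted values of the arrays nearly coincide and the same probes lack a value, and between sets both differ. Outside set D, described below, this is what quantile normalization of each set on its own leaves. Set A held embryonic stem cell line B6 with 15859 probes and a median intensity of 434 on its dimmest array, and set B held MEF2 EV and OKM+EV with 15506 probes and medians from 391.2 to 392.4. Set C held OKM with SOX1, SOX2, SOX3 or GMNN, with 14419 probes and medians from 370.3 to 371.3. Set D held MEF1 EV and every SKM group, with 14562 probes, medians from 400.8 to 416.1 and 5 negative values. Its sorted values coincided less closely, with a median deviation of 0.723 percent against 0.0184 to 0.0573 percent in the other sets. The reason is not known. Set E held uninfected fibroblasts, 3 induced pluripotent stem cell lines and embryonic stem cell line R1, with 14394 probes and medians from 295.9 to 296.2. Whether a difference in median between sets comes from scaling or from centring is unknown. Set and group cannot be told apart between sets, so tests were made within a set only. Values between sets, after quantile normalization over the 9896 probes with a value on every array, are given with no test.

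Of 19426 probes, 15539 carried 1 gene symbol, and 3887 without one were left out. A current symbol named 13971 probes, a unique synonym 1538, and 30 kept the platform's name, for 13852 genes in all. The probe with the highest mean over the arrays stood for a gene with several probes, of which there were 1531. Each gene was tested where all arrays compared held a value, which left 11989 genes in set E, 10011 in set D, 11948 in set B and 11189 in set C. No pair of arrays held identical values.

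Values were taken as log2 of intensity plus 32. For a gene near the background in 1 group, the size of its log2 fold change depends on this pseudocount. limma 3.58.1 in R 4.3.3 fitted a mean per group over all 49 arrays, with 32 contrasts and an intensity trend in the variance. Adjusted p-values are Benjamini-Hochberg over all genes of a contrast, with a threshold of 0.05, and all tests were two-sided. A mean over several lines or factors weighted each equally. Gene lists were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists of a contrast, for lists with at least 5 measured genes. Called lists were tested again with an estimated correlation, and a call is said to be lost only where that p is given. Where a called list has a single count of changes, its count adjusted over the list alone was the same.

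The fit, the comparisons, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. For the comparisons of pluripotent lines, of SKM+EV and OKM+EV with their fibroblasts, and for the mean over substitutes, the rule named the 8 largest rises and 8 largest falls. For other comparisons it named 5 of each. Each gene had to pass the threshold, its arrays could not overlap between the sides, and the brighter side's mean had to lie above the median of all genes. The 16 factor genes and up to 4 passing members per described list were added.

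The 23 lists covered pluripotency, primed epiblast, germline, fibroblast, epithelial, keratinocyte, ectoderm, mesendoderm, hepatocyte, adipocyte, myeloid, endothelial, skeletal muscle, and neural crest with glia and melanocyte genes. Further lists covered cell cycle, p53 and senescence, interferon response, inflammatory genes, TGF-beta and actin targets, imprinted genes, cholesterol synthesis and glycolysis. The remaining list had 1 measured gene and was not tested.

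The sets changed the plan in places. Line B6 was left out of the means over pluripotent and embryonic stem cell lines. OKM with SOX1, SOX2, SOX3 or GMNN could not be tested against OKM+EV or MEF2 EV, nor MEF1 EV against MEF2 EV. Instead, SOX1, SOX3 and GMNN were compared with OKM+SOX2 in set C, a choice made after the sets were seen.

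The fit was tested on simulated data with 200 changed genes in 10 draws and each set's own noise. For OCT4+SKM against SKM+EV it recovered 10.6 percent of the changes simulated below 1 log2 unit, 66.6 percent of changes of 1 and 96.4 percent of changes of 2, with 7 false calls. A fit of set D alone recovered 27.5, 82.5 and 97.9 percent, with 7.9 false calls. In set D the fit over all arrays therefore missed more of the smaller changes, and a gene that did not pass may still have changed. Set E was not simulated. For OKM+EV against MEF2 EV it made 1423.6 false calls on average, and a fit of set B alone made 0 but recovered 0.455 percent of changes of 2. For OKM+SOX1 against OKM+SOX2 it made 157 false calls, and a fit of set C alone made 3.2 and recovered 82.0 percent of changes of 2. The median residual SD on the log2 scale was 0.386 in set B and 0.222 in set C, against 0.160 in set D and 0.142 in set E. For sets B and C the counts of a fit within the set are therefore given too, and a gene is said there to have risen or fallen where it passed in both fits.

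The alternatives were equal array medians, quantile normalization over all arrays, a filter for genes above their array's median in at least 2 arrays, and a pseudocount of 128. The others were the mean of a gene's probes, no intensity trend, arrays of the own set only, a replicate block, leaving out each array in turn, the estimated correlation, and MIXL1 left out of the mean over substitutes. Chosen after seeing the data were all probes tested on their own, line means as replicates with R1 as the lone embryonic stem cell line, and CEBPa, HNF4a and GRB2 left out of the mean over substitutes. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.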

Results

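The arrays measured gene expression in mouse fibroblasts infected with reprogramming factors and in pluripotent stem cell lines. Embryonic fibroblasts (MEF) were taken from skin of limbs and tails. The factors were delivered with a doxycycline-inducible lentiviral system. SKM stands for SOX2, KLF4 and MYC, OKM for OCT4, KLF4 and MYC, and EV for an empty vector. Fibroblasts with EV alone came as MEF1 EV, the reference for OCT4 substitutes, and MEF2 EV, the reference for SOX2 substitutes, with 2 arrays each. SKM was combined with EV, OCT4, GATA6, SOX7, PAX1, CEBPa, HNF4a, GRB2 and MIXL1 on 2 arrays each and with GATA4 on 3. OKM was combined with EV on 3 arrays and with SOX1, SOX2, SOX3 or GMNN on 2 arrays each. The uninfected MEF, the induced pluripotent stem cell (iPSC) lines G6Gm, G3 and Dlx3RNAi, and embryonic stem cell (ESC) line R1 had 2 arrays each, and ESC line B6 had 3. The labels name 5 pluripotent lines, of which the 4 in set E are compared with the MEF.

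Dlx3, a homeobox gene of skin and placenta and by its name the target in iPSC line Dlx3RNAi, had an intensity of 319 ± 91.5 (SD, n = 2) in that line, with arrays at 254 and 384. It stood at 118 ± 36.3 in the uninfected MEF, 266 ± 47.4 in G6Gm, 375 ± 107 in G3 and 573 ± 59.3 in R1 (SD, n = 2 each). The difference between Dlx3RNAi and R1 was -0.81 on the log2 scale and did not pass the test (adjusted p = 0.072), nor did the differences from G3 (-0.21, adjusted p = 0.682) and G6Gm (0.22, adjusted p = 0.808). Against the uninfected MEF Dlx3 was higher in Dlx3RNAi (1.22, adjusted p = 0.0020). In sets A to D its group means ran from 149 ± 50.6 in GATA4+SKM (SD, n = 3) to 377 ± 32.4 in CEBPa+SKM (SD, n = 2). Whether the Dlx3 probe lies in the part an RNA interference sequence would target is not known.

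Of the 16 factor genes, 13 had a named probe. Sox2, a core pluripotency factor, rose from 114 ± 12.8 in the uninfected MEF (SD, n = 2) to 5552 ± 1427 in the 4 lines (SD, n = 8), and had no value in sets B, C and D. Pou5f1, which encodes OCT4, stood at 164 ± 8.15 in OCT4+SKM and 118 ± 15 in SKM+EV, and without OCT4 at 173 ± 34.7 in MEF1 EV, 208 ± 7.73 in HNF4a+SKM and 223 ± 7.75 in MIXL1+SKM (SD, n = 2 each). The probes did not follow the introduced factors. Gata4 stood at 315 ± 76.6 in GATA4+SKM (SD, n = 3) and 1092 ± 11.6 in SKM+EV, and Gata6 at 1808 ± 198 in GATA6+SKM and 2349 ± 17.7 in SKM+EV. Klf4 was at 1693 ± 42.2 in SKM+EV and 3592 ± 114 in MEF1 EV. Sox1 was at 82.1 ± 11.2 in OKM+SOX1 and 114 ± 34.3 in OKM+SOX2, and Sox3 at 152 ± 13.2 in OKM+SOX3 and 154 ± 43.4 in OKM+SOX2. Grb2 was at 2882 ± 269 in GRB2+SKM and 2905 ± 527 in SKM+EV. Cebpa and Mixl1 had no value in set D and Gmnn none in set C, Pax1 had a value in set A alone, and Myc, Sox7 and Hnf4a had no named probe. Whether these probes match the introduced sequences is not known, so they do not check the infection.

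The first question was how the pluripotent lines differ from the fibroblasts. Pluripotency, germline and glycolysis genes were higher in the 4 lines, and fibroblast genes lower. Upp1, a uridine phosphorylase, stood at 12779 ± 4384 in the lines (SD, n = 8) and 80.9 ± 3.42 in the uninfected MEF (SD, n = 2), a log2 fold change of 6.75 (SE 0.20, adjusted p = 8.26e-16). The glucose transporter Slc2a3 stood at 18669 ± 6103 against 229.8 ± 17.4 (log2 fold change 6.08). The growth factor Ptn, pleiotrophin, stood at 114 ± 76 in the lines and 12249 ± 1149 in the MEF (log2 fold change -6.59, SE 0.16, adjusted p = 4.29e-17). Of 11989 genes, 6931 changed, 3444 upward and 3487 downward, and 1317 rose and 1455 fell at least 2-fold.

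The other largest rises were in the X-linked homeobox gene Rhox5 (log2 fold change 6.50), the NAD synthesis enzyme Qprt (5.91), Pgf (5.83), the oocyte gene Ooep (5.25), Sox2 (5.22) and the germ cell gene Dazl (5.04). The other largest falls were in Cd40lg (-5.45), elastin Eln (-5.11), Lrrn3 (-4.98), Osr1 (-4.95), Samd5 (-4.92), the matrix protein Mgp (-4.85) and Dlk1 (-4.76).

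In the pluripotency list 8 of 9 measured genes rose and 1 fell (adjusted p = 9.52e-12). Zfp42 rose by 4.94, Utf1 by 4.69, Pou5f1 by 2.16 and Klf2 by 2.01 on the log2 scale, and Nr0b1 fell by 1.12. In the germline list 8 of 9 rose and 1 did not pass (adjusted p = 3e-18), with Rhox9 at 3.73 and Tdrd12 at 3.07. In the fibroblast list 1 gene rose, 20 fell and 4 did not pass (adjusted p = 1.26e-11). Pdgfra fell by 3.97, S100a4 by 3.74, Snai2 by 3.36 and Col3a1 by 3.16, and Sparc, a matrix glycoprotein, rose by 0.76. The epithelial list had 8 rises, with Spint2 at 3.29 and St14 at 3.01, a fall of Cdh3 (-2.04), and 1 gene that did not pass (adjusted p = 2.76e-06; adjusted p = 0.0714 with an estimated correlation). Of 17 imprinted genes 3 rose, 12 fell and 2 did not pass (adjusted p = 2.32e-15). H19 fell by 4.42, the cell cycle inhibitor Cdkn1c by 4.24 and Mest by 2.79, and Phlda2 rose by 3.36. Glycolysis genes rose in 9 of 10 cases (adjusted p = 1.89e-06), with the glucose transporter Slc2a1 at 3.53 and the hexokinase Hk2 at 2.53. Of 21 cell cycle genes 16 rose, 1 fell and 4 did not pass (adjusted p = 0.0019), with Ccne1 at 2.21, Mcm5 at 1.96 and Ccne2 at -0.74. Of 16 inflammatory genes 12 rose, 2 fell and 2 did not pass (adjusted p = 0.000205), with Ptgs2 at 2.91, Icam1 at 2.35 and Vcam1 at -2.94. Of 14 cholesterol synthesis genes 9 fell, led by Sc5d (-2.18) and Mvk (-2.07), and 5 did not pass (adjusted p = 0.000264). Apart from the epithelial list, these calls held with an estimated correlation, and the counts were identical adjusted over the list alone.

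The other lists were not called in this comparison. Rises and falls were 6 and 4 of 17 in the ectoderm list (adjusted p = 0.735), 3 and 4 of 16 in the mesendoderm list (0.94), 4 and 2 of 7 in the primed epiblast list (0.338), and 2 and 2 of 7 in the hepatocyte list (0.829). They were 4 and 5 of 12 for adipocyte genes (0.555), 2 and 9 of 19 for myeloid genes (0.547), 7 and 3 of 14 for endothelial genes (0.555), and 7 and 1 of 14 for keratinocyte genes (0.208). They were 2 and 3 of 11 for skeletal muscle (0.891), 2 and 2 of 5 for neural crest, glia and melanocyte genes (0.829), and 4 and 4 of 16 for p53 and senescence genes (0.989). The interferon list had 5 and 5 of 19 (0.829), and the TGF-beta and actin list 6 and 5 of 12 (0.555).

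**Figure D1:**
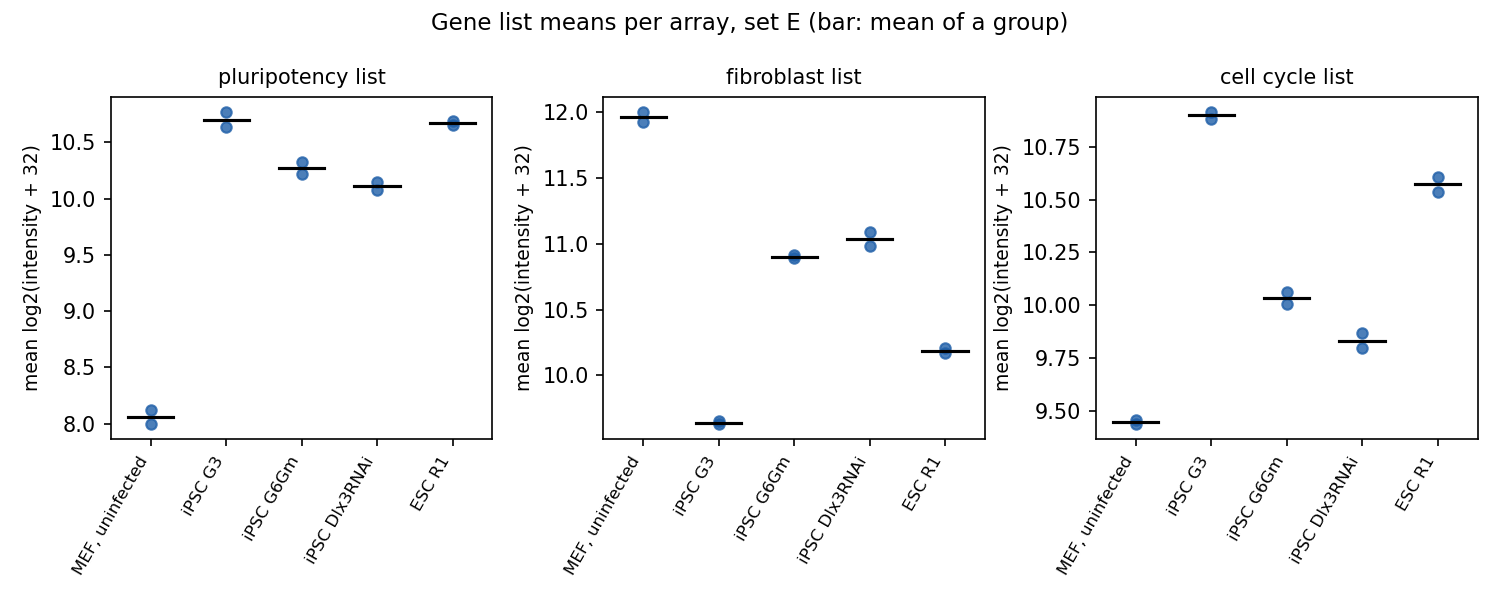
Mean log2 of intensity plus 32 over the genes of a list (vertical axis) for each array of the uninfected MEF, 3 iPSC lines and ESC line R1; dots are arrays and bars are group means. The pluripotency list lies higher and the fibroblast list lower in the lines than in the MEF.

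The next question was how the iPSC lines differ from an ESC line. Against R1, the mean of the 3 iPSC lines had higher fibroblast and interferon response genes and lower epithelial and cell cycle genes. None of these list calls held with an estimated correlation (adjusted p = 0.147, 0.0982, 0.214 and 0.0982). The lines differed in the fibroblast list, where against R1 14 of 25 genes rose in G6Gm over all genes and 15 adjusted over the list alone (adjusted p = 9.01e-10; adjusted p = 0.0584 with an estimated correlation). In Dlx3RNAi 16 rose over all genes, and 18 rose and 1 fell adjusted over the list alone (adjusted p = 3.44e-13). In G3 none rose, and 8 fell over all genes and 13 adjusted over the list alone (adjusted p = 2.15e-10; adjusted p = 0.0576 with an estimated correlation). Rpl29, a ribosomal protein gene, stood at 1900 ± 508 in the iPSC lines (SD, n = 6) and 116 ± 6.06 in R1 (SD, n = 2), a log2 fold change of 3.66 (SE 0.20, adjusted p = 5.69e-14). Of 11989 genes, 1621 changed, 862 upward and 759 downward. The count was 673 without R1 replicate 1 and 722 without R1 replicate 2. With line means as replicates, 3 lines against 1, limma called 0 genes and 427 had an unadjusted p under 0.05.

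The other largest rises were in Ubd (3.13), Cemip (2.28), the chemokine Ccl7 (2.24), Rbms3 (2.12), Apoa2 (2.09), Fgfbp1 (1.99) and Thbs2 (1.89). The largest falls were in the glutamate receptor subunit Grin1 (-2.02), the polycomb gene Scml2 (-1.98), Dnase1 (-1.96), Rpl15 (-1.96), Rhox13 (-1.93), the receptor Kit (-1.81), Plekhg1 (-1.80) and Kbtbd11 (-1.71). In the fibroblast list 7 of 25 rose and 18 did not pass (adjusted p = 0.00106; adjusted p = 0.147 with an estimated correlation), with Col5a2 at 1.07, Cdh2 at 0.89 and Snai2 at 0.82. In the epithelial list 5 of 10 fell (adjusted p = 0.00426; adjusted p = 0.214 with an estimated correlation), led by St14 (-1.30) and Krt19 (-0.90). Of 21 cell cycle genes 6 fell over all genes and 7 adjusted over the list alone (adjusted p = 0.00477; adjusted p = 0.0982 with an estimated correlation), led by Bub1 (-0.92) and Ccnb2 (-0.85). Of 19 interferon genes 5 rose and 1 fell over all genes, and 7 rose and 1 fell adjusted over the list alone (adjusted p = 0.00426; adjusted p = 0.0982 with an estimated correlation). Bst2 rose by 1.13, Cxcl10 by 1.11 and Irf7 by 1.06, and Oasl1 fell by 0.52. Of 10 glycolysis genes 2 fell, Slc2a3 (-0.71) and Slc16a3 (-0.54), with an adjusted p = 0.036 for the list and an adjusted p = 0.0982 with an estimated correlation. The pluripotency list was not called (adjusted p = 0.0747). Of its 9 genes Nr0b1 rose by 0.95, Tbx3 fell by 1.13, Zfp42 was among 3 that fell (-0.73), and Sox2 did not pass (-0.38, adjusted p = 0.14).

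The arm for OCT4 substitutes asks what SKM does to fibroblasts and what each added factor changes. SKM+EV had keratinocyte and epithelial genes far above MEF1 EV. Keratin Krt17 stood at 17538 ± 5441 in SKM+EV and 111 ± 21.6 in MEF1 EV (SD, n = 2 each), a log2 fold change of 6.92 (SE 0.25, adjusted p = 8.35e-20). Krt8, a keratin of simple epithelia, stood at 8058 ± 3183 against 38 ± 3.78 (6.80), and Krt14 of basal keratinocytes at 48858 ± 3256 against 1240 ± 211 (5.27). Of 10011 genes, 1961 changed, 997 upward and 964 downward, and 369 rose and 318 fell at least 2-fold. The count was 1121 without MEF1 EV replicate 1 and 1284 without SKM+EV replicate 2.

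Other largest rises were in the epidermal genes Lgals7 (6.48), Cnfn (6.32), Sfn (5.53) and Sprr1b (5.52), and in Mal (5.48). The largest falls were in the mitochondrial mutase Mmut (-4.55), Nrk (-3.33), the collagen Col8a2 (-3.07), Tmem178 (-3.04), Car3 (-3.00), the adipokine Adipoq (-2.93), Adamts17 (-2.92) and Col26a1 (-2.85). Adipoq (adjusted p = 0.0187) did not pass when any of the 4 arrays was left out, with an adjusted p from 0.0698 to 0.096.

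In the keratinocyte list 9 of 12 rose, none fell over all genes and 1 fell adjusted over the list alone (adjusted p = 4.52e-38). Lor and Sprr1a (3.57), of the cornified envelope, rose, and Krt5 did not pass (0.00). In the epithelial list 8 of 11 rose and 3 did not pass (adjusted p = 2.13e-13), with Krt19 at 3.08. Of 15 inflammatory genes 9 rose over all genes and 11 adjusted over the list alone (adjusted p = 2.72e-10), with Lcn2 at 3.04, the neutrophil chemokine Cxcl2 at 2.71 and the monocyte chemokine Ccl2 at 1.70. Of 11 glycolysis genes 6 rose (adjusted p = 0.00276), led by the lactate exporter Slc16a3 (2.31). Of 13 p53 and senescence genes 6 rose over all genes and 8 adjusted over the list alone (adjusted p = 3.38e-06; adjusted p = 0.0974 with an estimated correlation), with Perp at 3.10, Gadd45a at 1.09 and Cdkn2a at 1.06. Of 25 fibroblast genes 1 rose and 10 fell over all genes, and 1 rose and 13 fell adjusted over the list alone (adjusted p = 0.000627). Cdh2 fell by 1.43, Col5a2 by 1.28 and Snai2 by 1.04, and S100a4 rose by 0.58. Of 22 interferon genes 8 fell over all genes and 9 fell and 1 rose adjusted over the list alone (adjusted p = 0.00345), with Ifi44 at -1.98, Oasl2 at -1.27 and Irf7 at -1.08. Of 15 imprinted genes 7 fell and 1 rose (adjusted p = 0.00283; adjusted p = 0.122 with an estimated correlation), with Mest at -2.83, Peg3 at -1.65 and Phlda2 at 2.54. The ectoderm list was not called (adjusted p = 0.577). Of its 11 genes Map2 (-1.28) and Zic1 (-1.14) fell and 9 did not pass, and its median was 0.06 where its mean was -0.20. The mesendoderm list (0 rises, 3 falls of 16, adjusted p = 0.324) and the pluripotency list (0 rises, 1 fall of 8, adjusted p = 0.446) were not called.

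**Figure D2:**
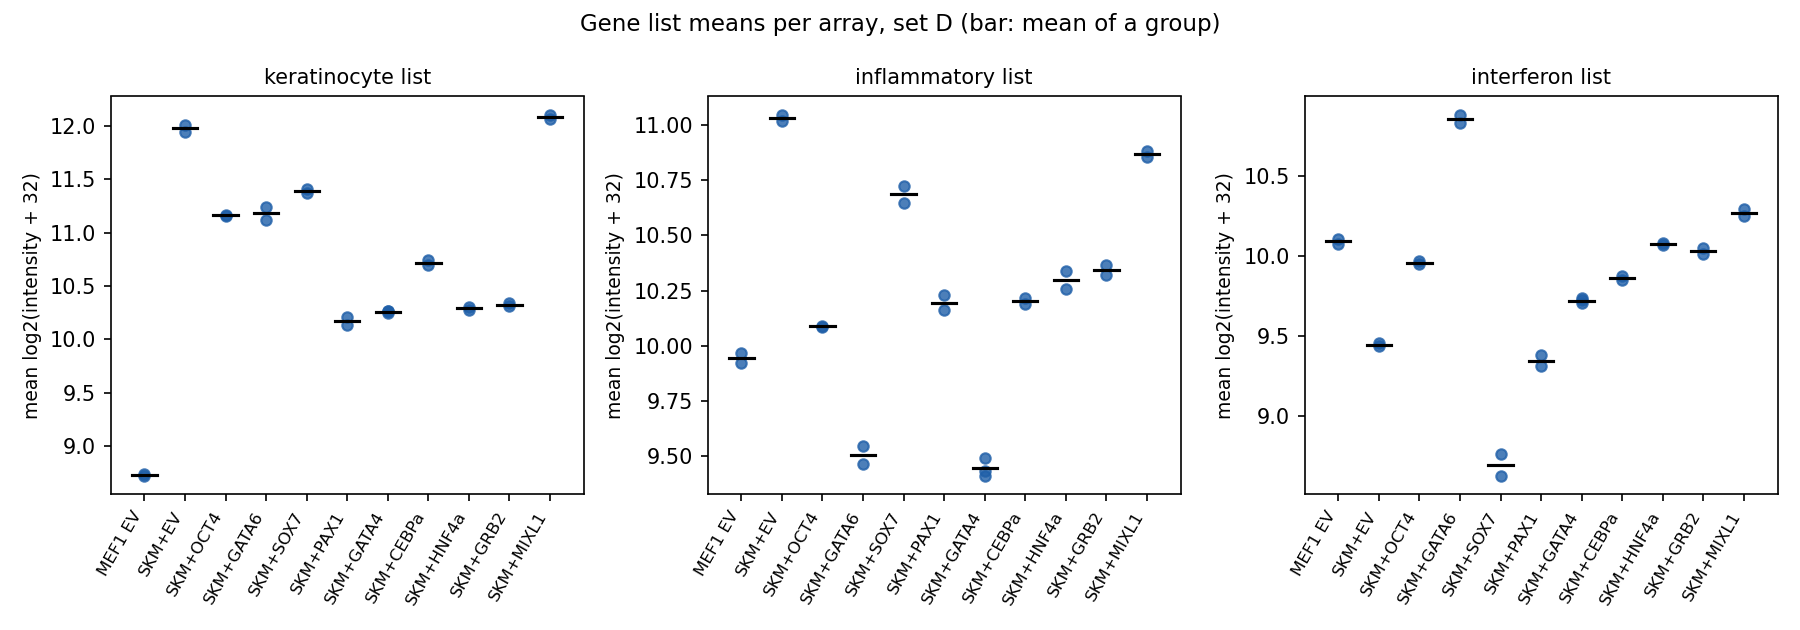
Mean log2 of intensity plus 32 over the genes of a list (vertical axis) for each array of MEF1 EV and the SKM groups of set D; dots are arrays and bars are group means. The keratinocyte list lies above MEF1 EV in every SKM group and below SKM+EV in most groups with an added factor.

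By its label, OCT4+SKM combined all 4 classical factors. Against MEF1 EV, OCT4+SKM also had higher keratinocyte and epithelial genes and lower fibroblast genes. Krt8 (6.66), Krt17 (6.31), Mgarp (6.17), Lgals7 (6.04) and Actn4 (5.99) had the largest rises. Vmn1r45 (-2.92), Scn7a (-2.86), Car3 (-2.76), Nrk (-2.67) and the collagen Col14a1 (-2.66) had the largest falls. Of 10011 genes 2233 changed, 1160 upward and 1073 downward. The count was 1367 without MEF1 EV replicate 1 and 1361 without OCT4+SKM replicate 1. In the fibroblast list 12 of 25 fell over all genes and 13 adjusted over the list alone (adjusted p = 6.85e-06). In the epithelial list 8 of 11 rose over all genes and 10 adjusted over the list alone (adjusted p = 1.55e-14), and in the keratinocyte list 8 of 12 rose and, adjusted over the list alone, 8 rose and 1 fell (adjusted p = 1.28e-22). Of 11 glycolysis genes 4 rose and 1 fell over all genes, and 5 and 1 adjusted over the list alone (adjusted p = 0.0402). The cell cycle list, with 5 rises of 18 (adjusted p = 0.0402; adjusted p = 0.0628 with an estimated correlation), and the p53 and senescence list, with 2 rises of 13 (adjusted p = 0.0282; adjusted p = 0.54 with an estimated correlation), were called with the preset correlation.

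Against SKM+EV, OCT4+SKM had higher interferon genes, higher Nefm and Rbfox3, and lower keratinocyte and inflammatory genes. Coagulation factor F5 stood at 2443 ± 277 in OCT4+SKM and 138 ± 41.7 in SKM+EV (SD, n = 2 each), a log2 fold change of 3.88. Larger rises were in Mgarp (5.12), the neurofilament Nefm (5.06), the neuronal splicing factor Rbfox3 (4.93) and Entpd3 (4.11). The largest falls were in Cited1 (-3.68), the epidermal genes Sprr1b (-2.91), Lce1b (-2.83) and Crct1 (-2.68), and in Edn2 (-2.61). Cited1 (adjusted p = 0.00475) did not pass without SKM+EV replicate 1 (adjusted p = 0.212) or without OCT4+SKM replicate 2 (adjusted p = 0.0700). Of 10011 genes 1103 changed, 529 upward and 574 downward. The count was 653 without SKM+EV replicate 1, 707 without OCT4+SKM replicate 1 and 621 without OCT4+SKM replicate 2.

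In the keratinocyte list 5 of 12 fell over all genes and 6 adjusted over the list alone (adjusted p = 0.000146), with Sprr1a at -2.14 and Lor at -1.94. Of 15 inflammatory genes 8 fell (adjusted p = 8.54e-14), with Lcn2 at -2.41, Cxcl2 at -1.78, the gelatinase Mmp9 at -1.66 and Il6 at -1.27. Of 22 interferon genes 5 rose (adjusted p = 0.00493), with Irf7 at 1.41 and Ifi44 at 1.14. Of 15 imprinted genes 5 rose over all genes and 6 adjusted over the list alone (adjusted p = 0.000431; adjusted p = 0.0861 with an estimated correlation), with Ascl2 at 2.10, Mest at 1.47 and Phlda2 at 1.35. The p53 and senescence list had 4 falls of 13 (adjusted p = 0.00898; adjusted p = 0.335 with an estimated correlation). The cholesterol list had 4 falls of 11 over all genes and 5 adjusted over the list alone (adjusted p = 0.0492; adjusted p = 0.244 with an estimated correlation). The ectoderm list had 2 rises of 11, Map2 (1.63) and Nrcam (1.23), and was not called (adjusted p = 0.975). The pluripotency list had 1 rise of 8, Nr0b1 (0.51), and was not called (adjusted p = 0.236).

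The cardiac troponin Tnnt2 rose with GATA6, GATA4 and SOX7 in place of OCT4. In GATA6+SKM the vascular phosphatase Ptprb stood at 2712 ± 104 against 36 ± 9.65 in SKM+EV (SD, n = 2 each, log2 fold change 5.34), and cardiac troponin Tnnt2 rose by 4.82 (adjusted p = 5.98e-19). Podxl (5.27), Akap5 (5.26) and Serpinb6b (4.47) also rose most, and Hp (-5.74), Agtr2 (-4.69), Egfl6 (-4.30), Sprr1b (-4.15) and Slpi (-4.15) fell most. Of 10011 genes 2202 changed, 1179 upward and 1023 downward, against 1270 without SKM+EV replicate 1 and 1254 without GATA6+SKM replicate 2. In the fibroblast list 1 of 25 rose, Cdh2 (2.21), and 15 fell over all genes and 17 adjusted over the list alone (adjusted p = 3.3e-10), with Pdgfra at -2.74, Fap at -2.07 and Col3a1 at -2.03. Of 22 interferon genes 15 rose over all genes and 18 adjusted over the list alone (adjusted p = 1.21e-12), with Irf7 at 2.87, Rsad2 at 2.70 and Ifit1 at 2.62. Of 15 inflammatory genes 11 fell (adjusted p = 7.23e-15), with the stromelysin Mmp3 at -4.03. Of 12 keratinocyte genes 1 rose and 6 fell (adjusted p = 0.0102). In the skeletal muscle list 3 of 8 rose, the troponins Tnnt2, Tnni1 (3.56) and Tnnc1 (2.78), which heart muscle also uses, and 4 rose and 1 fell adjusted over the list alone (adjusted p = 1.08e-07; adjusted p = 0.15 with an estimated correlation).

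In GATA4+SKM the liver glycoprotein gene Ahsg stood at 7360 ± 1272 (SD, n = 3) against 91.6 ± 13.7 in SKM+EV (SD, n = 2), a log2 fold change of 5.89. Sostdc1 (4.92), Tnnt2 (4.80), Rragd (4.55) and Ap1s3 (4.49) followed, and Kprp (-4.89), Cited1 (-4.79), Sprr1b (-4.47), Sprr2d (-4.40) and Crct1 (-4.15) fell most. Of 10011 genes 5391 changed, 2903 upward and 2488 downward, against 3558 without SKM+EV replicate 1. In the hepatocyte list 3 of 7 rose, Ahsg, Rbp4 (1.20) and Apoa2 (0.57), and F10 fell (-1.54; list adjusted p = 0.00392; adjusted p = 0.548 with an estimated correlation). The keratinocyte list had 10 falls of 12 over all genes and 11 adjusted over the list alone (adjusted p = 4.4e-08), the inflammatory list 13 falls of 15 (adjusted p = 2.18e-12), and the fibroblast list 2 rises and 14 falls of 25 (adjusted p = 0.00234). The cell cycle list had 13 rises and 1 fall of 18 over all genes and 13 and 2 adjusted over the list alone (adjusted p = 0.0127; adjusted p = 0.0646 with an estimated correlation). The imprinted list had 1 rise and 8 falls of 15 (adjusted p = 0.000309; adjusted p = 0.0587 with an estimated correlation), and the skeletal muscle list 3 rises and 3 falls of 8 (adjusted p = 0.0463; adjusted p = 0.911 with an estimated correlation).

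In SOX7+SKM the vascular genes Ptprb (3.56) and Bcl6b (3.28), Sostdc1 (3.56), Zscan18 (3.56) and Uchl1 (2.97) rose most, and Cited1 (-4.27), Sfrp2 (-3.33), Dpt (-3.26), Cfb (-3.24) and Lor (-3.22) fell most. Zscan18 (adjusted p = 0.0225) was at 0.13 without SOX7+SKM replicate 2 (adjusted p = 0.774), and did not pass without SKM+EV replicate 1 (adjusted p = 0.109) or replicate 2 (adjusted p = 0.0882). Cited1 did not pass without SKM+EV replicate 1 (adjusted p = 0.0987). Of 10011 genes 1210 changed, 634 upward and 576 downward, against 543 without SKM+EV replicate 1 and 596 without SOX7+SKM replicate 1. The interferon list had 8 falls of 22 over all genes and 12 adjusted over the list alone (adjusted p = 6.27e-06), with Bst2 at -1.25, Ifi44 at -1.08 and Irf7 at -0.97. The skeletal muscle list had 4 rises of 8 over all genes and 5 adjusted over the list alone (adjusted p = 2.85e-06), with Tnnt2 at 2.49. The TGF-beta and actin list had 5 rises of 12 over all genes and 6 rises and 1 fall adjusted over the list alone (adjusted p = 0.00101), with Ankrd1 at 1.73 and the TGF-beta feedback gene Skil at 1.11. The keratinocyte list had 3 falls of 12 over all genes and 1 rise and 4 falls adjusted over the list alone (adjusted p = 0.000487).

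PAX1+SKM had the chaperone Clu at 29663 ± 684 against 2017 ± 98.4 in SKM+EV (SD, n = 2 each, log2 fold change 3.86), and lower keratins. Prtn3 (2.79), Rab15 (2.54), Ccdc22 (2.39) and Srgn (2.38) also rose, and Khdc1a (-3.86), Kprp (-3.82), Krt14 (-3.80), Krt17 (-3.67) and Nfkb1 (-3.27) fell most. Of 10011 genes 1574 changed, 961 upward and 613 downward, against 777 without SKM+EV replicate 1 and 704 without PAX1+SKM replicate 1. The keratinocyte list had 7 falls of 12 (adjusted p = 2.29e-23), the epithelial list 5 falls of 11 over all genes and 7 adjusted over the list alone (adjusted p = 3.08e-07), with Krt19 at -2.54, and the inflammatory list 9 falls of 15 over all genes and 10 adjusted over the list alone (adjusted p = 7.48e-12). The fibroblast list had 6 rises of 25 (adjusted p = 0.0409). The p53 and senescence list had 4 falls of 13 over all genes, with 1 rise more adjusted over the list alone, and was called downward (adjusted p = 0.0319; adjusted p = 0.501 with an estimated correlation) with a mean of -0.24 and a median of 0.04.

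CEBPa+SKM, HNF4a+SKM and GRB2+SKM had Pfdn4 and Mmut among their largest named rises, and Sprr2d and Kprp among their largest falls. Pfdn4, a prefoldin subunit, stood at 3.83 ± 1.66 in SKM+EV and at 6649 ± 113, 7952 ± 906 and 7234 ± 383 in the 3 groups (SD, n = 2 each), and since its level in SKM+EV lies near the lowest values of the set, the size of its log2 fold change depends on the pseudocount and is not given. Mmut, among the largest falls in SKM+EV against MEF1 EV, rose by 4.77, 4.75 and 4.76. H2ac23 rose by 3.92 with CEBPa and 4.28 with HNF4a, Ap2a2 by 3.50 and 3.88, and Tcn2 by 4.09 with HNF4a. Uchl1 rose by 3.51 with CEBPa and 3.42 with GRB2, and Twf2 (3.25) and Ext2 (3.18) with GRB2. The epidermal genes Sprr2d (-3.74, -4.03 and -4.09) and Kprp (-3.24, -3.92 and -3.77) fell with all 3 factors. Lor fell by 3.11 with CEBPa and 3.45 with GRB2, and Krt6b by 3.35 with HNF4a and 3.41 with GRB2. C8b (-2.90) and Calm4 (-2.88) fell with CEBPa, Sprr1b (-3.33) and Nfkb1 (-3.33) with HNF4a, and Idi2 (-3.03) with GRB2. Of 10011 genes 3459 changed with CEBPa (1992 upward and 1467 downward), 4248 with HNF4a (2291 and 1957) and 4033 with GRB2 (2316 and 1717). Without SKM+EV replicate 1 these were 1985, 2663 and 2395, and the CEBPa count was 2144 without its replicate 2 and the GRB2 count 2488 without its replicate 1. The 6 arrays of these groups had medians from 412.6 to 416.1, above those of all other arrays of set D (400.8 to 408). A batch shared by these arrays cannot be told apart from the factors.

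Of 18 cell cycle genes 10 rose with CEBPa, 10 with HNF4a and 9 with GRB2 (adjusted p = 0.000112, 0.000699 and 0.000124), with Top2a at 2.56 with HNF4a and 2.48 with GRB2. Keratinocyte genes fell in 8, 10 and 11 of 12 cases over all genes and 8, 11 and 11 adjusted over the list alone (adjusted p = 3.75e-07, 6.51e-09 and 2.19e-10). Epithelial genes fell in 6, 6 and 7 of 11 cases over all genes and 6, 7 and 7 adjusted over the list alone, with 1 rise with HNF4a (adjusted p = 0.000246, 0.00411 and 1.33e-05). Inflammatory genes fell in 8, 8 and 7 of 15 cases over all genes and 11, 8 and 7 adjusted over the list alone (adjusted p = 7.88e-06, 0.000891 and 0.000517). Of 11 cholesterol synthesis genes 6 rose with each factor over all genes, and adjusted over the list alone 7 rose and 1 fell with CEBPa, 7 rose with HNF4a and 6 rose with GRB2 (adjusted p = 0.0155, 0.0063 and 0.0309), with Fdps at 2.53 with GRB2. With an estimated correlation the cholesterol list had an adjusted p = 0.434 with CEBPa, an adjusted p = 0.276 with HNF4a and an adjusted p = 0.511 with GRB2. HNF4a+SKM differed from the mean of CEBPa+SKM and GRB2+SKM in 46 genes, 37 higher and 9 lower. The higher ones included the intestinal keratin Krt20 (2.61), the claudins Cldn7 (1.91) and Cldn15 (1.49), Gmps (3.11), the water channel Aqp11 (1.66), Calml4 (1.31) and Vnn1 (1.15).

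MIXL1+SKM differed least from SKM+EV among the groups with an added factor by count. The neuropeptide Gal (4.33), Krt27 (3.34, adjusted p = 3.75e-16), Gsta3 (3.22), Tprg (2.90) and Sox21 (2.73) rose most, and Hpgd (-1.87), Dpt (-1.55), Pi16 (-1.52), Khdc1a (-1.46) and Clec3b (-1.42) fell most. Clec3b (adjusted p = 0.00337) did not pass without SKM+EV replicate 2 (adjusted p = 0.0674) or MIXL1+SKM replicate 2 (adjusted p = 0.0577). Of 10011 genes 208 changed, 104 in each direction, against 75 without SKM+EV replicate 1, 105 without MIXL1+SKM replicate 1 and 82 without its replicate 2. Of 22 interferon genes 7 rose over all genes and 11 adjusted over the list alone (adjusted p = 9.04e-19), with Irf7 at 2.02 and Ifi44 at 1.76. Of 11 epithelial genes 2 rose over all genes and 4 adjusted over the list alone (adjusted p = 4.78e-05). The keratinocyte list had no change that passed (adjusted p = 0.42).

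Over the mean of the 8 factors other than OCT4 (17 arrays against 2), keratinocyte and inflammatory genes were lower than in SKM+EV. Kprp, a gene of the cornified envelope, stood at 831 ± 1257 (SD, n = 17) against 5761 ± 275 (SD, n = 2), a log2 fold change of -3.40 (adjusted p = 2.19e-10). Sprr2d (-3.17), Krt6b (-2.60), Krt16 (-2.50), Asprv1 (-2.43), Hpgd (-2.40), Sprr2h (-2.39) and Calm4 (-2.26) followed. The rises were smaller and were led by H2ac23 (1.68), Ccdc22 (1.52), Csrp2 (1.27), Prkg2 (1.16), Akap12 (0.99), Hspb1 (0.87), Scx (0.86) and Stbd1 (0.83). The keratinocyte list had 10 falls of 12 (adjusted p = 1.11e-13), with Lor at -2.77 and Krt17 at -1.95, and the inflammatory list 12 falls of 15 (adjusted p = 6.09e-13), with Lcn2 and Mmp9 at -1.56 each. Of 22 interferon genes 8 rose over all genes and 9 adjusted over the list alone (adjusted p = 0.0235). The epithelial list had 1 rise and 6 falls of 11 (adjusted p = 0.0123; adjusted p = 0.0511 with an estimated correlation), and the cell cycle list 8 rises of 18 (adjusted p = 0.00544; adjusted p = 0.0511 with an estimated correlation). The ectoderm list was not called (adjusted p = 0.994). Of its 11 genes Nes (0.97) and Map2 (0.74) rose, Zic2 (-1.03) fell and 8 did not pass, with a mean of -0.00 and a median of -0.23. Of 10011 genes 2833 changed, 1660 upward and 1173 downward, against 633 without SKM+EV replicate 1 and 1666 with CEBPa, HNF4a and GRB2 left out of the mean. Without SKM+EV replicate 1, Prkg2 (adjusted p = 0.0758), Hspb1 (adjusted p = 0.151) and Scx (adjusted p = 0.0894) did not pass, and without replicate 2 neither did Prkg2 (adjusted p = 0.0601) and Scx (adjusted p = 0.141).

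All comparisons with SKM+EV share its 2 arrays. The keratinocyte list was called lower in 8 of the 9 comparisons, the exception being MIXL1+SKM, and the same 8 were called against either SKM+EV array alone. All 9 still rest on the same controls, so these are not 8 independent calls. Against MEF1 EV the keratinocyte list was higher in every SKM group. There 8 of 12 genes rose and 2 fell with GATA6 (adjusted p = 1.28e-10), 9 rose and 2 fell with GATA4 (adjusted p = 0.00118), and 9 rose and 3 fell with HNF4a (adjusted p = 0.00124). These calls held with an estimated correlation. The interferon list, lower in SKM+EV than in MEF1 EV, was not called against MEF1 EV for OCT4+SKM, with 1 rise and 2 falls of 22 (adjusted p = 0.661), or MIXL1+SKM, with 5 rises over all genes and 4 adjusted over the list alone (adjusted p = 0.455), where it was higher than in SKM+EV. It was not called for GATA4, CEBPa, HNF4a or GRB2 with SKM either. It was higher with GATA6, with 9 rises and 1 fall (adjusted p = 0.00446), and lower with SOX7, with 16 falls over all genes and 17 adjusted over the list alone (adjusted p = 8.08e-08), and with PAX1, with 8 and 9 falls (adjusted p = 5.97e-06). The inflammatory list, with a mean of 1.09 in SKM+EV against MEF1 EV, was higher there with SOX7 too (0.74, adjusted p = 0.000277). With MIXL1 it was also higher (0.93, adjusted p = 2.0e-07). With OCT4 (0.15, adjusted p = 0.659), GATA6, PAX1, GATA4, CEBPa, HNF4a and GRB2 it was not called against MEF1 EV.

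Whether the substitutes change the genes that OCT4 changes was the question of the shared calls. GATA6 and OCT4 both raised 186 genes (n1 × n2 / N = 62.3) and both lowered 235 (58.7), SOX7 110 (33.5) and 164 (33.0), PAX1 162 (50.8) and 216 (35.1), and GATA4 332 (153) and 305 (143). CEBPa and OCT4 both raised 111 genes (n1 × n2 / N = 105) and both lowered 160 (84.1), HNF4a 128 (121) and 177 (112), GRB2 154 (122) and 175 (98.4), and MIXL1 42 (5.50) and 70 (5.96). Simulated unchanged groups shared at most 0.01 such genes on average, but they hold almost no calls, so this number is no reference for comparisons with many calls. Opposite directions were counted for 119 genes with GATA6, 76 with SOX7, 51 with PAX1 and 122 with GATA4. They were counted for 264 with CEBPa, 289 with HNF4a, 273 with GRB2 and 12 with MIXL1. For opposite directions n1 × n2 / N was not computed, so these counts do not rank factors with unlike numbers of calls. The correlation of log2 fold changes with those of OCT4, across genes, which are not independent replicates, was 0.306 for GATA6, 0.352 for SOX7, 0.417 for PAX1, 0.432 for GATA4 and 0.330 for MIXL1. It was 0.0741 for CEBPa, 0.0982 for HNF4a and 0.134 for GRB2. Simulated unchanged groups gave 0.550 with GATA4 and at most 0.504 with the others. In them only the shared control arrays link the comparisons, so these correlations are no reference for groups with many calls either. The covariance was 0.102 for GATA6, 0.0854 for SOX7, 0.106 for PAX1, 0.184 for GATA4, 0.0256 for CEBPa, 0.0384 for HNF4a, 0.0486 for GRB2 and 0.0519 for MIXL1, against 0.0225 to 0.0228 simulated. The differences from the simulated covariance ran from 0.00307 with CEBPa to 0.161 with GATA4. In a split chosen after seeing the data, 1 control array served OCT4 and the other the substitute, both ways round. The covariance was then 0.0543 and 0.0925 for GATA6, 0.0445 and 0.0687 for SOX7, 0.0663 and 0.0891 for PAX1, 0.115 and 0.194 for GATA4, and 0.0240 and 0.0223 for MIXL1. It was -0.0238 and 0.0174 for CEBPa, -0.0204 and 0.0396 for HNF4a, and -0.00712 and 0.0469 for GRB2, so for these 3 the sign depended on the control array. In the split CEBPa and OCT4 both raised 49 genes each way (n1 × n2 / N = 55.3 and 50.6), HNF4a 51 (64.7) and 54 (62.5), and GRB2 64 (62.6) and 71 (60.4). CEBPa and OCT4 both lowered 96 (39.9) and 100 (26.4), HNF4a 105 (54.8) and 106 (40.4), and GRB2 102 (48.0) and 101 (32.6). GATA6 and OCT4 both raised 85 (36.5) and 109 (26.0) and both lowered 134 (27.3) and 133 (22.8). The split shares no control array, and each side of it holds only 1. With both control arrays in every comparison, part of the excess may come from the shared controls. Compared with OCT4+SKM itself, 2305 genes differed in GATA6+SKM, 1606 in SOX7+SKM, 1722 in PAX1+SKM, 4879 in GATA4+SKM, 4180 in CEBPa+SKM, 4640 in HNF4a+SKM, 4353 in GRB2+SKM and 935 in MIXL1+SKM.

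The arm for SOX2 substitutes asks what OKM does to fibroblasts. OKM+EV had far higher epithelial and keratinocyte genes than MEF2 EV and far lower myeloid genes, which are markers of another cell type. The calls of these lists did not hold with an estimated correlation (adjusted p = 0.0604, 0.0604 and 0.328). Krt8 stood at 9753 ± 2659 in OKM+EV (SD, n = 3) and 63.4 ± 24 in MEF2 EV (SD, n = 2), a log2 fold change of 6.66 (adjusted p = 1.48e-21; 0.00083 within the set). The macrophage receptor Marco stood at 303 ± 195 against 36419 ± 328 (-7.02). Of 11948 genes 4876 passed, 2363 upward and 2513 downward. Within set B alone 665 passed, 370 upward and 295 downward, of which 662 passed in both fits.

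Other largest rises were in Fgfbp1 (6.66), Krt17 (6.53), S100a14 (5.27), 2610528A11Rik (5.18), Lgals7 (5.17), Krt14 (5.01) and Sptssb (4.73). The other largest falls were the macrophage genes C1qa (-6.11), Adgre1 (-6.00), Csf1r (-5.78), Fcgr3 (-5.68), Slc11a1 (-5.68) and Mpeg1 (-5.54), and Sstr5 (-5.39). In the epithelial list 14 of 18 genes were higher, 12 of them within the set (adjusted p = 9.39e-17; adjusted p = 0.0604 with an estimated correlation), with Dsp at 3.46, Krt19 at 3.23, Spint1 at 2.85 and Rab25 at 2.82. In the keratinocyte list 11 of 15 were higher, 8 of them within the set (adjusted p = 7.02e-18; adjusted p = 0.0604 with an estimated correlation), with Sprr1a at 4.06 and Sfn at 3.83. In the myeloid list all 18 were lower, 15 of them within the set, with a mean of -4.09 (adjusted p = 3.28e-41; adjusted p = 0.328 with an estimated correlation). Of 16 inflammatory genes, a list that myeloid cells also express in part, 8 were higher and 1 lower, and within the set 5 and 1 (adjusted p = 0.00119; adjusted p = 0.328 with an estimated correlation). Cxcl5 rose by 3.48, Lcn2 by 3.13, Ptgs2 by 2.27 and Ccl7 by 1.68, and Mmp9 fell by 2.46. Of 15 p53 and senescence genes 10 were higher and 1 lower, and 2 higher within the set (adjusted p = 0.00156; adjusted p = 0.328 with an estimated correlation), Perp (2.49) and Gadd45a (2.20). Of 13 adipocyte genes 2 were higher and 8 lower, and 2 lower within the set (adjusted p = 0.0213; adjusted p = 0.49 with an estimated correlation), Plin1 (-3.95) and Dgat2 (-2.36). The interferon list, with 10 genes higher and 1 lower of 19 and none within the set, was called with the preset correlation (adjusted p = 0.032; adjusted p = 0.803 with an estimated correlation). Of 13 pluripotency genes 5 were higher and 3 lower, and within the set Fbxo15 (3.97), Fgf4 (2.64) and Tdgf1 (2.47) rose, without a call for the list (adjusted p = 0.189). The mesendoderm list, with 3 genes higher and 3 lower of 19, none within the set and a mean of 0.06, was not called (adjusted p = 0.912). For the called lists, counts adjusted over the list alone were those over all genes. OKM+EV replicate 3 correlated at 0.843 and 0.884 with replicates 1 and 2, across genes, which correlated at 0.986 with each other.

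**Figure D3:**
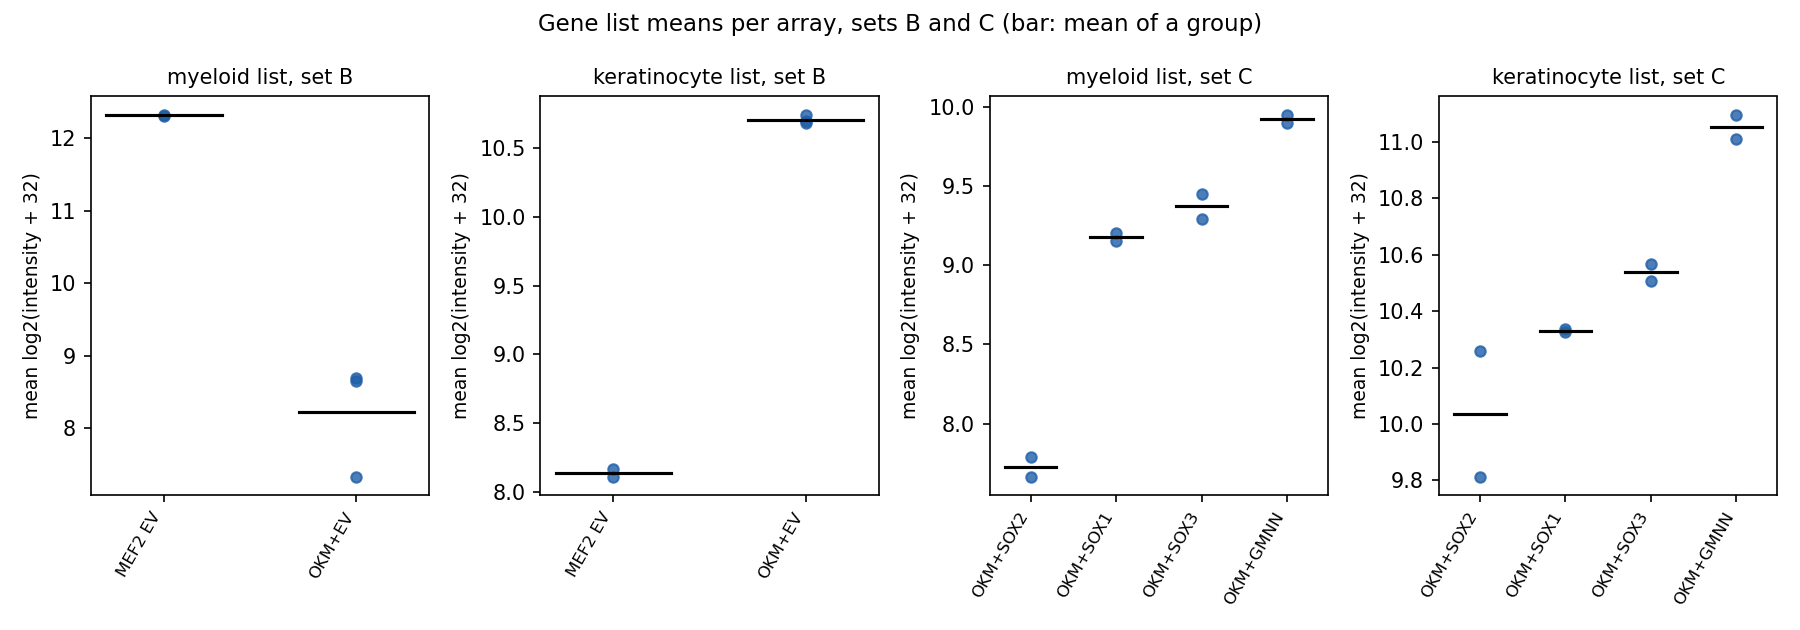
Mean log2 of intensity plus 32 over the genes of a list (vertical axis) for each array of sets B and C; dots are arrays and bars are group means. The myeloid list is highest in MEF2 EV, at 12.3, and lies at 8.69, 8.66 and 7.33 on the OKM+EV arrays.

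The remaining question was how SOX1, SOX3 and GMNN compare with SOX2 beside OKM. Myeloid genes, markers of another cell type, were higher than in OKM+SOX2 with all 3, and beside GMNN keratinocyte genes too. Whether these cultures differed in their share of macrophages was not tested, so the myeloid difference is not assigned to the factors. The macrophage lectin Clec10a rose by 4.04 with SOX1, 4.05 with SOX3 and 4.93 with GMNN, and stood at 1901 ± 947 with SOX1 against 78.1 ± 2.89 with SOX2 (SD, n = 2 each). Of 11189 genes 640 passed with SOX1 (410 upward and 230 downward; 22 within set C, 21 in both fits), 707 with SOX3 (384 and 323; 27 and 25) and 808 with GMNN (489 and 319; 225 and 207). Without OKM+SOX2 replicate 1 the counts were 94, 113 and 339, and without its replicate 2 they were 1207, 1447 and 1290. They were 293 and 97 without SOX1 replicate 1 and 2, 156 and 230 without SOX3 replicate 1 and 2, and 326 and 335 without GMNN replicate 1 and 2. The OKM+SOX2 arrays, the controls of all 3 comparisons, correlated at 0.905 across genes. Replicate 1 stood apart, at 0.890 to 0.901 with the arrays of the other groups in set C against 0.970 to 0.978 for replicate 2.

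With SOX1 the cochaperone Dnaja3 fell by 2.36. With SOX3 the neural gene Sox21 fell by 2.30, Msc by 1.93, Pcolce2 by 1.76 and Spink2 by 1.68. Pcolce2 did not pass without OKM+SOX2 replicate 1 (adjusted p = 0.127) or SOX3 replicate 1 (adjusted p = 0.0604), nor Spink2 without OKM+SOX2 replicate 1 (adjusted p = 0.0895) or SOX3 replicate 2 (adjusted p = 0.0510). With GMNN Marco rose by 4.44 and C1qa by 3.86, and Msc fell by 2.92, the forkhead factor Foxd1 by 2.89, Upp1 by 2.62, Pmch by 2.06 and Ifi27l2a by 2.00. Pmch did not pass without GMNN replicate 1 (adjusted p = 0.0778). The rule for named genes also took Slirp, Prkar2b, Blvrb, Msln, Xpo4, Mfap4, Trh and Zswim1 with SOX1, Pcolce, Cd68, Tmem43, Hadh and Zswim1 with SOX3, and Msln and Selenop with GMNN, which did not pass within the set.

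Of 13 myeloid genes 7 were higher with SOX1, 9 with SOX3 and 9 with GMNN over all genes, and 8, 12 and 10 adjusted over the list alone (adjusted p = 3.27e-19, 4.09e-21 and 2.91e-36). Within the set 5, 7 and 10 passed. Csf1r rose by 2.51 with SOX1, 1.69 with SOX3 and 3.39 with GMNN, and Fcgr3 by 2.74 with SOX1 and 3.41 with GMNN. With GMNN, where myeloid genes were higher, 8 of 15 keratinocyte genes were higher, 6 of them within the set (adjusted p = 8.27e-12), with Krt14 at 1.64 and Krt17 at 1.62. Of 20 interferon genes 6 were lower over all genes, and 10 lower and 1 higher adjusted over the list alone, with 5 lower within the set (adjusted p = 0.000228; adjusted p = 0.0652 with an estimated correlation), with Oas2 at -1.74, Irf7 at -1.08 and Bst2 at -0.96. Of 15 inflammatory genes 6 were higher with GMNN over all genes, 7 adjusted over the list alone and 1 within the set (adjusted p = 0.000228; adjusted p = 0.13 with an estimated correlation). Of 19 ectoderm genes 4 were lower over all genes, with 1 higher too adjusted over the list alone, and none passed within the set (adjusted p = 0.0158; adjusted p = 0.195 with an estimated correlation), and of 13 pluripotency genes 3 were lower, none within the set (adjusted p = 0.0158; adjusted p = 0.385 with an estimated correlation). With SOX1, 3 of 17 imprinted genes were lower over all genes, 4 adjusted over the list alone and none within the set (adjusted p = 0.00125; adjusted p = 0.687 with an estimated correlation). In 4 further lists called with SOX3, no gene passed within the set. The fibroblast list had 1 gene higher and 6 lower of 26 over all genes and 1 and 7 adjusted over the list alone (adjusted p = 0.00491; adjusted p = 0.504 with an estimated correlation), and the pluripotency list 2 lower of 13 over all genes and 5 adjusted over the list alone (adjusted p = 0.0089; adjusted p = 0.504 with an estimated correlation). The epithelial list had 1 gene higher of 20 (adjusted p = 0.00491; adjusted p = 0.151 with an estimated correlation), and the keratinocyte list 1 of 15 over all genes and 4 adjusted over the list alone (adjusted p = 0.00188; adjusted p = 0.151 with an estimated correlation).

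Values between sets have no test, since set and group cannot be told apart. Over the 8488 genes on all arrays the SD of log2 differences was 1.11 between MEF1 EV and MEF2 EV, 1.05 between the ESC lines B6 and R1, and 0.638, 0.540, 0.453 and 0.544 between OKM with SOX2, SOX1, SOX3 or GMNN and OKM+EV. The mean of OKM with SOX1, SOX3 and GMNN lay 0.03 from OKM+EV over 12 mesendoderm genes and 1.19 above it over 10 myeloid genes, all 10 of them higher. Over these myeloid genes OKM+SOX1 lay 0.84 above OKM+EV (7 higher, 3 lower), OKM+SOX3 1.04 and OKM+GMNN 1.68 (10 higher each), while OKM+SOX2 lay at -0.68 with all 10 lower. Over 10 myeloid genes MEF1 EV lay at -5.07 relative to MEF2 EV.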

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

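The comparisons of the iPSC lines with each other were added after the data were seen, while the tests of fibroblast-like cells had their bounds fixed before their results. The 3 iPSC lines, each set against the same uninfected MEF, differed from one another in many genes by limma, which is a difference between groups under the same contrast. Fibroblast genes were higher and cell cycle genes lower in Dlx3RNAi and G6Gm than in G3. Dlx3RNAi differed from G3 in 3034 genes (1415 higher and 1619 lower), and G6Gm differed from G3 in 2359 genes (1281 higher and 1078 lower). Dlx3RNAi differed from G6Gm in 339 genes (122 higher and 217 lower). Against the uninfected MEF 4814 genes changed in G6Gm, 6264 in G3 and 5787 in Dlx3RNAi. The counts between single lines were not recomputed with an array left out.

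Against G3, the largest rises included the matrix genes Aspn (3.04 in Dlx3RNAi and 2.73 in G6Gm), Crispld2 (3.04 and 2.78) and Cemip (2.88 and 2.77), and Ipp fell most (-4.41 and -4.28), with both arrays of each line beyond both of G3. Of 25 fibroblast genes 20 rose in Dlx3RNAi over all genes and 23 adjusted over the list alone (adjusted p = 1.8e-27), and 18 and 21 rose in G6Gm (adjusted p = 2.59e-27). Mmp2, a gelatinase of connective tissue, rose by 2.51 and 2.50, and Col6a1 by 2.52 and 1.90. Of 21 cell cycle genes 16 fell in Dlx3RNAi over all genes and 21 adjusted over the list alone (adjusted p = 4.04e-11), and 11 and 15 fell in G6Gm (adjusted p = 6.97e-09). Krt8 fell by 2.36 and 2.56 and Pou5f1 by 0.95 and 1.85. In G6Gm alone among the lines Gpd1, an enzyme of glycerol metabolism, stood at 29471 on both arrays, a rise of 7.25 over G3 and a fall of 7.43 for Dlx3RNAi against G6Gm. Whether this probe detects Gpd1 alone or also a sequence of the vectors was not tested, so the value is that of the probe. Mmp13, a collagenase, fell by 3.76 in G6Gm against G3 and rose by 4.08 in Dlx3RNAi against G6Gm.

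Some iPSC cultures may have held cells like the uninfected MEF, and this was weighed for the higher fibroblast genes. The list's 21 genes with a usable difference would need a median MEF share of 34.8 percent in G6Gm (quartiles 17.1 and 60.5) and 54.8 percent in Dlx3RNAi (13.3 and 87.2). The 100 genes that set the MEF most apart from G3 imply 6.12 percent (1.10 and 15.1) and 6.65 percent (1.21 and 13.6), which is 17.6 percent of the list's share in G6Gm and 12.1 percent in Dlx3RNAi. Both ratios lie below the bound fixed beforehand, which argues against cells like the uninfected MEF as the whole cause. Mitomycin-treated feeder MEF with another profile, partial differentiation and the factors used for each line stay open and were not tested.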

How the results depend on the processing

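Of the 9 list results and 210 named genes and contrasts tested again, none reversed its direction under any alternative that gave it a value. Quantile normalization over all arrays gave a value for 141 of the 210. The other list results and the genes named between single iPSC lines were not part of this check. A count has no direction, but its balance of rises and falls turned within the own set in places. OKM+EV against MEF2 EV had 2363 rises and 2513 falls in the main fit and 370 and 295 within the set. SKM+EV against MEF1 EV had 997 and 964, then 1634 and 1770. The balance also turned for OCT4+SKM against MEF1 EV and for the pluripotent lines against the MEF. The covariance of CEBPa, HNF4a and GRB2 with OCT4 turned negative in 1 of the 2 ways of splitting the SKM+EV arrays (-0.0238, -0.0204 and -0.00712). The tests with this split, with line means, with all probes and with CEBPa, HNF4a and GRB2 left out were chosen after seeing the data. Equal array medians, the brightness filter, the mean of a gene's probes, no intensity trend and the pseudocount of 128 left the 27 counts and list results within 1.5 times or on their side of the threshold, and so did all probes for 18 of 18 and MIXL1 left out for 3 of 3. Of 2877 values for 210 named genes and contrasts, 2787 kept their side of the threshold and 90 passed it no more, 56 of them with 1 array left out, 15 within the own set, 18 with the block and 1 with the mean of a gene's probes; 0 reversed. The named genes were chosen as the largest changes that passed, so these numbers say little about the other called genes. With 1 array left in a group, that array is assumed to vary like the other groups. Precision is limited by the number of arrays, and dim genes lie near the background of the arrays, which was not given.

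Quantile normalization over all 49 arrays, which tests 8488 genes and so fewer, gave 729 changed genes for OCT4, 779 for SOX7, 873 for PAX1, 125 for MIXL1 and 1824 for the mean of 8, each against SKM+EV. Within the own set the counts were 3577 for iPSC against R1, 3404 for SKM+EV and 3707 for OCT4+SKM against MEF1 EV, and 665 for OKM+EV. Against SKM+EV they were 2299 for OCT4, 3507 for GATA6, 2482 for SOX7, 3273 for PAX1, 687 for MIXL1 and 4526 for the mean of 8, and against OKM+SOX2 22 for SOX1, 27 for SOX3 and 225 for GMNN. The median residual SD (0.386 in set B, 0.222 in set C, 0.160 in set D and 0.142 in set E) differs between sets, and a fit within the set uses its own. Line means as replicates, 3 lines against 1, gave 0 genes by limma and 427 at an unadjusted p under 0.05. Leaving CEBPa, HNF4a and GRB2 out of the mean of 8 gave 1666. With an estimated correlation the OKM+EV keratinocyte list kept its mean of 2.57 (adjusted p = 0.0604) and the myeloid list its mean of -4.09 (adjusted p = 0.328), but neither was called. The cause was not tested.

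With 1 array left out, counts ranged from 673 to 1423 for iPSC against R1, from 1121 to 1662 for SKM+EV and 1361 to 1741 for OCT4+SKM against MEF1 EV, from 5073 to 6822 for the lines against MEF and 3457 to 6759 for OKM+EV. Against SKM+EV they ranged from 621 to 768 for OCT4, 1254 to 2005 for GATA6, 543 to 1069 for SOX7, 704 to 1187 for PAX1, 3558 to 5052 for GATA4, 1985 to 2956 for CEBPa, 2663 to 3694 for HNF4a, 2395 to 3428 for GRB2, 75 to 142 for MIXL1 and 633 to 3009 for the mean of 8. Without SKM+EV replicate 1 they were lowest for SOX7, GATA4, CEBPa, HNF4a, GRB2, MIXL1 and the mean of 8. Against OKM+SOX2 they ranged from 94 to 1207 for SOX1, 113 to 1447 for SOX3 and 326 to 1290 for GMNN. Fewer arrays were used, but some counts rose. For OKM+EV the count was 6759 without replicate 3, against 4876 with all arrays, and the upper ends against OKM+SOX2 also lie above the counts with all arrays. The cause was not tested.

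With the replicate number as a replicate block within the own set, the counts were 3463 for iPSC against R1, 3235 for SKM+EV and 3577 for OCT4+SKM against MEF1 EV. Against SKM+EV they were 2170 for OCT4, 3383 for GATA6, 2318 for SOX7, 3109 for PAX1, 569 for MIXL1 and 4383 for the mean of 8, and against OKM+SOX2 11 for SOX1, 11 for SOX3 and 150 for GMNN. The numbers do not pair the arrays. Same-numbered deviations correlated at 0.173 in set B (1 pair of groups) and from -0.127 to 0.0773 in set C. They correlated from -0.504 to 0.516 in set D and from -0.241 to 0.238 in set E. In set D, correlations of this size in both directions leave open a deviation shared by arrays of different groups, which the p-values do not allow for.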

Other observations

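The tests on CEBPa+SKM, HNF4a+SKM and GRB2+SKM and the test without OKM+EV replicate 3 were chosen only after their results were seen, and the bounds for the share of macrophage genes were fixed before. In OKM+GMNN, set against the mean of OKM with SOX1, SOX2 and SOX3, the macrophage receptor Marco (2.56) and the keratin Krt90 (2.44) were higher and Upp1 (-3.15) and Foxd1 (-2.35) lower in the fit over all arrays. Of 11189 genes 818 passed, 398 higher and 420 lower, and this count was not recomputed within the set or with an array left out. Of 15 keratinocyte genes 8 were higher over all genes and 9 adjusted over the list alone (adjusted p = 2.9e-09), of 13 myeloid genes 6 and 8 were higher (adjusted p = 1.71e-14), and of 20 interferon genes 7 were lower, with 8 lower and 1 higher adjusted over the list alone (adjusted p = 1.99e-05). Each of these lists had an adjusted p = 0.0551 with an estimated correlation.

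Between sets, with no test, ESC line B6 lay at -2.50 relative to R1 over 20 fibroblast genes, with 18 of them lower, and at -2.48 over 10 inflammatory genes, all 10 of them lower. Over 6 pluripotency genes it lay at 0.13. MEF1 EV lay 0.998 above MEF2 EV over 20 fibroblast genes, with 17 of them higher.

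Arrays of CEBPa+SKM, HNF4a+SKM and GRB2+SKM correlated with each other within the range of replicates over all groups of set D. Across genes, arrays of different factors among these 3 correlated at 0.987 to 0.994 (median 0.990), arrays of the same group in set D at 0.983 to 0.995 (0.988) and other pairs of groups in set D at 0.846 to 0.986 (0.921). One culture behind the HNF4a and GRB2 arrays is argued against by 64 genes that differed between them (limma), led by Gmps and Krt20. For CEBPa and GRB2 6 genes differed, too few to decide whether their arrays could hold RNA of 1 culture. A shared array processing batch stays open, since batch and groups cannot be told apart. Although 6 of the 6 arrays had a median above every other array of set D, this cannot decide it, as groups with like expression could share a median too. A like response to the 3 factors stays open too and was not tested.

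Myeloid genes were lower in OKM+EV than in MEF2 EV, all 18 of the list, with Marco at 36419 and other macrophage genes high in MEF2 EV. The MEF2 EV cultures might have held macrophages, and OKM+EV fewer. Of 24 macrophage genes outside the list, written down before the test, 18 or 75 percent lay below -1 on the log2 scale (median -2.75), against 8.32 percent of all genes, which lies between the bounds fixed beforehand and leaves this open; Clec4d (-5.33), Clec4n (-4.99) and Rac2 (-4.88) were the lowest. A deviating OKM+EV replicate 3 is argued against as the cause, since the list's mean was -3.64 without it. A change of these genes within the fibroblasts was not tested, no sort is given in the labels, and between sets MEF2 EV lay 3.78 above the uninfected MEF over 10 myeloid genes.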
